A study of Arabidopsis thaliana with 4 samples.

How the data were processed

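RNA was extracted with TRIzol from 1 g of 2-week-old seedlings and sequenced as mRNA libraries, per the labels' protocols. The authors aligned reads with HISAT2 to TAIR10 and used edgeR, per the submitters' processing notes, which give no versions. The gene counter, its strand setting, the annotation and the filters are not given in the sources used here. The deposited values are a normalized signal per gene and library, with 1 column for each library and no pooling. They are fractional, their column totals lie close together, and no division by gene length shows, so they were treated as read abundance scaled to a common library size. The scaling step is not given in the sources used here.

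Low values were tested for whole-read steps: with a tolerance of 0.1, 25.9%, 79.6%, 59.1% and 80.5% of the low values in cmt3 replicate 1, cmt3 replicate 2, labelled triple mutant replicate 1 and labelled triple mutant replicate 2 were whole multiples of one step. Reads were therefore not recovered, the depth per library is unknown, no count test was used and no interval or limit of detection that needs depth is given. Values under 1e-10 were set to 0. Of the 32548 genes in the table all 32548 identifiers matched locus tags of the TAIR10.1 reference annotation, from which symbols, products and coordinates were taken. Coordinates are 1-based. The table holds 4 further per-sample columns that match no sample given here. Summaries of their values were seen when the table was first checked, and no fit, test or reported value uses them.

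The samples were grouped by their titles into cmt3 and tcx5 tcx6 cmt3, with 2 libraries each. The design written before the data were examined named a count test for whole-number values and, for normalized values, limma on a log scale, and the second was used because the values are not counts. Genes with a value of 1 or more in 2 or more libraries were kept, which left 23666. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3, with the group as the only term and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates changes in low genes. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333 (two-sided), so none is given for single genes.

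Gene lists were fixed before the data were examined: 22 lists with 332 genes, of which 330 are in the table and 319 were tested. The lists cover the mutated genes, DNA methylation maintenance, RNA-directed DNA methylation, DNA demethylation, DREAM and E2F, replication, mitosis, repair, meiosis, histones, methylation-silenced loci, and markers of organs, cell types and stress. The 21 lists with 3 or more tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 21 lists. Camera passed 10 of them. The mutated gene list did not pass (camera adjusted p = 0.273). Camera with an estimated correlation passed 0 of the 21, and fry passed 9. Planned lists of chloroplast, mitochondrial and transposable element genes could not be formed from the values and annotation used here.

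Genes named in the text were all members of the mutated gene and methylation maintenance lists, the 10 largest rises and the 10 largest falls among called genes with a mean of 1 or more in a genotype and no overlap between libraries, and up to 4 members of each other list with the smallest p. Other genes, such as CLSY3, NRPD1, NRPE1, DRM1, DRM2, ATHB13, HTA6, HTA13, TCX2, TCX3, TCX7, TSO1, MCM6, CDC45, CYCB2;1, ZYP1A, ZYP1B, H1.3, WRKY38, KIN2, RAB18, RD29A, IRT1 and AT1G69760, and the genes of the product words, were named after their values were seen.

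The fit was tested on simulated data with 200 changed genes among 23417. It recovered 4.48% of the genes changed 1.5-fold, 46.3% of those changed 2-fold and 90.9% of those changed 4-fold, with 0 false calls among 94. The data gave 2005 calls, far more than the genes changed here, so these shares do not carry over to the data. A simulated list raised 1.5-fold was the 1 list called among 21. Promoter sites were searched in the 500 bp upstream of the annotated gene start on both strands and compared by two-sided Fisher tests with Python 3.11.15 and SciPy 1.17.1. Genes are not independent replicates in such tests. Alternatives were quantile normalization, no filter or a filter at 5, a pseudocount of 0.1, limma without the trend, a replicate block, leaving out each library, thresholds of 0.01 and of 2-fold, an estimated correlation, fry and a 1000 bp promoter. Centring each library on the median of genes with a mean of 100 or more was chosen after seeing the data.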

Results

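Gene-level mRNA abundance was measured by mRNA sequencing in 2-week-old Arabidopsis thaliana seedlings grown on MS plates under 16 h of light and 8 h of dark at 22 °C. The 4 libraries fell into 2 genotypes with 2 libraries each. The cmt3 seedlings are labelled as carrying a mutation in CMT3, the chromomethylase gene that maintains CHG methylation, and served as the control background. The libraries labelled tcx5 tcx6 cmt3 are labelled as also carrying mutations in TCX5 and TCX6, the CXC-domain proteins that bind DNA as part of the DREAM cell cycle repressor. The single comparison, between these genotypes, asks how gene expression differs with the labelled tcx5 and tcx6 mutations in a cmt3 background, and the series names genes for DNA methylation maintenance as its subject. Normalized values summed to 41106100 and 38264500 in the cmt3 libraries and to 39000000 and 39160800 in the labelled triple mutant libraries. The reads behind these values are unknown. Across tested genes the Pearson correlation of log2 values was 0.981 between the cmt3 replicates, 0.985 between the labelled triple mutant replicates and 0.968 to 0.969 between genotypes. Of the genes with a mean of 100 or more, 1.99% differed 2-fold or more between the cmt3 replicates and 0.126% between the labelled triple mutant replicates, against 5.05% to 5.52% across genotypes. No label says that replicates were separate batches of plants, so p-values measure the spread between these libraries, which may be technical.

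The mutated genes did not all follow the labels. TCX5 (AT4G29000, chromosome 4, 14293513 to 14297066, plus strand) fell from 703 ± 38.2 (SD, n = 2) in cmt3 to 250 ± 1.22 (SD, n = 2) in the labelled triple mutant, a log2 fold change of -1.49 ± 0.12 (SE; limma adjusted p = 0.00121). TCX6 (AT2G20110, chromosome 2, 8683979 to 8687283, plus strand) rose from 189 ± 12.6 to 976 ± 81.9 (SD, n = 2 each), a log2 fold change of 2.36 ± 0.13 (SE; limma adjusted p = 0.00044), which goes against its label. CMT3 (AT1G69770, chromosome 1, 26248118 to 26253687, minus strand), labelled as mutated in both genotypes, rose from 742 ± 113 to 1316 ± 38.3, a log2 fold change of 0.83 ± 0.12 (limma adjusted p = 0.00985). No wild-type sample is given here, so whether CMT3 abundance is reduced in either genotype cannot be told. The gene-level values do not show which part of a gene was transcribed, so a transcript upstream or downstream of an insertion is counted with the rest. Because of TCX6, the second genotype is called the labelled triple mutant throughout, and every direction below rests on that label. The gene next to CMT3, AT1G69760, also rose, from 502 to 915 (log2 fold change 0.87, limma adjusted p = 0.00404), while the neighbour on its other side, ATHB13, was at 928 and 1081 (log2 fold change 0.22, adjusted p = 0.259). CMT3 (adjusted p = 0.111) and AT1G69760 (0.0517) lost their calls in limma without the mean-variance trend, and all 3 mutated genes lost theirs without either labelled triple mutant library: without replicate 1 the adjusted p was 0.139 for TCX5, 0.138 for TCX6 and 0.281 for CMT3, and without replicate 2 it was 0.145, 0.14 and 0.303.

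**Figure D1:**
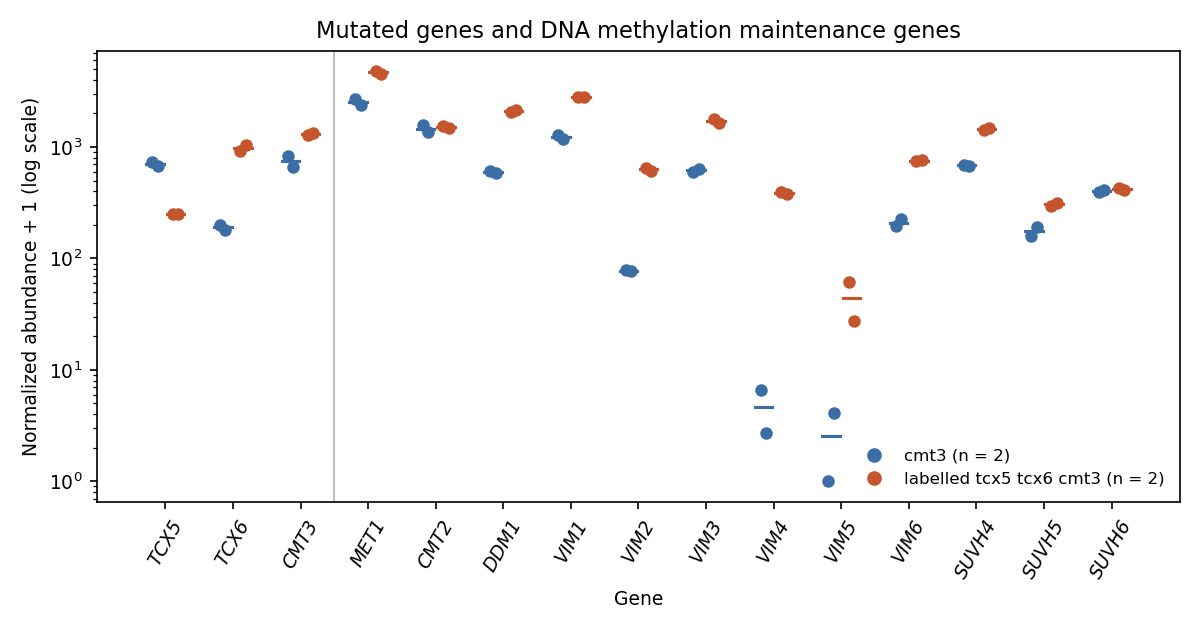
Normalized abundance plus 1 on a log axis for each library (points, 2 per genotype) and the genotype mean of those values (bars) for the mutated genes and the 12 DNA methylation maintenance genes. TCX5 was lower and TCX6 higher in the labelled triple mutant, 10 of the 12 maintenance genes were called higher, and CMT2 and SUVH6 lay close together in both genotypes.

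More genes rose than fell in the labelled triple mutant. Of 23666 tested genes, 1456 were higher and 549 lower at a limma adjusted p under 0.05, and 776 and 190 of these changed 2-fold or more on the log2(value + 1) scale. The libraries of the genotypes did not overlap for 50.1% of the tested genes, where chance gives 33.3%. The median log2 fold change of all tested genes was -0.02. Leaving out either labelled triple mutant library ended every call in this comparison: limma called 0 genes higher and 0 lower, with 2407 genes at an unadjusted p under 0.05 without replicate 1 and 2490 without replicate 2, against 4840 with all 4 libraries. Those fits have the cmt3 pair as their only measure of spread, and every gene named below as having risen or fallen lost its call in them. The fits without a cmt3 library have the labelled triple mutant pair as their only measure of spread. That pair lay closer together: 0.126% of the abundant genes compared above differed 2-fold or more within it, against 1.99% within the cmt3 pair. The lone cmt3 library is assumed to vary as little. Calls kept without a cmt3 library, here and below, therefore do not show that a result is robust.

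The largest rises were in genes that were near or at 0 in cmt3. TIL2 (AT2G27120, chromosome 2, 11581214 to 11594397), annotated as a DNA polymerase epsilon catalytic subunit, rose from 6.87 ± 1.13 to 998 ± 45.0 (SD, n = 2 each; log2 fold change 6.99 ± 0.26, limma adjusted p = 0.000308). BSU1 (AT1G03445, chromosome 1, 854410 to 859701), a serine/threonine phosphatase of brassinosteroid signalling, rose from 19.2 ± 10.8 to 1898 ± 253 (log2 fold change 6.66 ± 0.38). HDA18 (AT5G61070, chromosome 5, 24571095 to 24574387), a histone deacetylase, rose from 25.7 ± 4.597 to 1535 ± 51.4 (log2 fold change 5.86 ± 0.20). VIM4 (AT1G66040) rose from 3.68 ± 2.80 to 384 ± 13.6, the peroxidase family gene AT4G33870 from 4.602 ± 2.55 to 444 ± 14.8, and SPO11-2 (AT1G63990), which takes part in meiotic double-strand break formation, from 3.01 ± 2.35 to 254 ± 10.6. SPO11-2 overlaps AT1G08647 on the same strand and AT1G63980 on the opposite one, so its reads may be shared with them. The importin alpha gene IMPA-5 (AT5G49310) was at 3.35 and 0 in cmt3 and at 127 and 131 in the labelled triple mutant. Of the genes listed at 0 in both cmt3 libraries, the RNA helicase family gene AT1G58050 (chromosome 1, 21478590 to 21487839) was at 479 and 460, the leucine-rich repeat kinase gene AT1G24650 at 89.1 and 60.1, and the metal transporter gene NRAMP5 (AT4G18790) at 61.7 and 63.2. IMPA-5 was not called in limma without the trend (adjusted p = 0.0753).

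The largest falls were in genes that were at or near 0 in the labelled triple mutant. AT5G35480 (chromosome 5, 13687847 to 13689596), annotated as uncharacterized, fell from 508 ± 102 to 1.01 ± 0.288 (SD, n = 2 each; log2 fold change -7.98 ± 0.40, limma adjusted p = 0.000404). Its neighbour MRU1 (AT5G35490, chromosome 5, 13689817 to 13690548) fell from 412 ± 57.5 to 4.49 ± 3.73 (log2 fold change -6.42 ± 0.54). AT5G45570 (chromosome 5, 18471498 to 18475574), a gene of the Ulp1 protease family, fell from 791 ± 29.5 to 10.6 ± 4.02, and the uncharacterized gene AT5G15360 from 469 ± 38.04 to 6.96 ± 0.385. The Ta11-like non-LTR retrotransposon gene AT2G13450 (chromosome 2, 5598421 to 5599923) was at 154 and 168 in cmt3 and at 4.13 and 0 in the labelled triple mutant. Listed at 0 in both labelled triple mutant libraries were AT2G06845 (232 and 204 in cmt3), AT1G27570 (184 and 179), AT1G63540 (102 and 90.6), AT2G05350 (68.6 and 74.6) and the Ulp1 protease family gene AT5G28810 (35.1 and 89.4). AT2G06845 overlaps AT2G05015 on the opposite strand. AT2G13450 was not called in limma without the trend (adjusted p = 0.0848), without cmt3 replicate 1 (0.0863) or without cmt3 replicate 2 (0.0797).

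**Figure D2:**
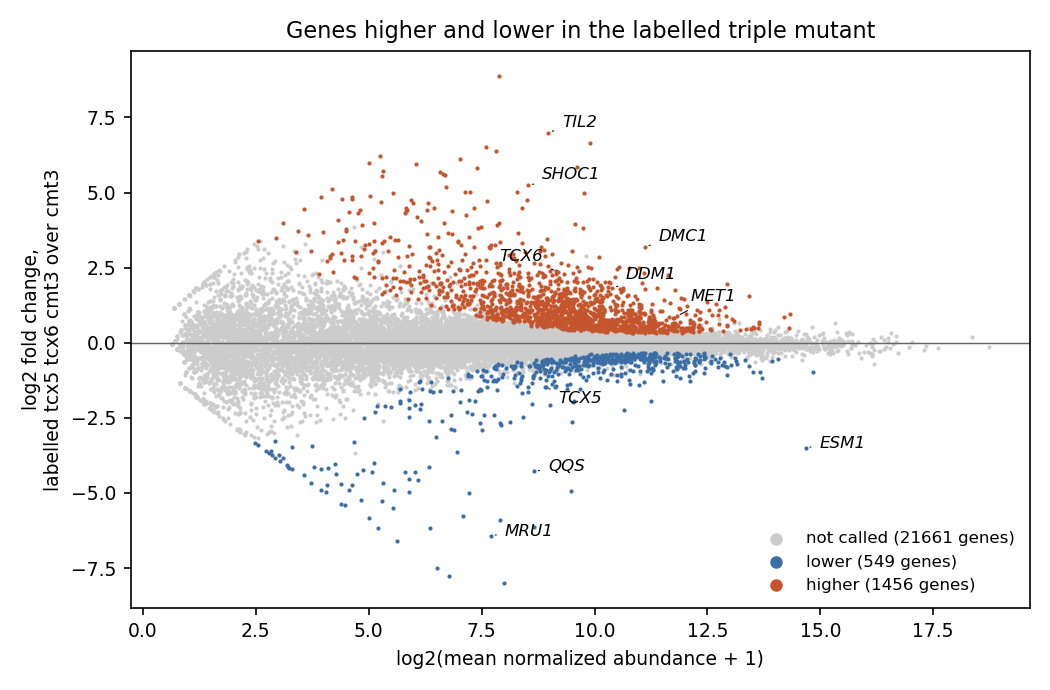
Log2 fold change of the labelled triple mutant over cmt3 (y axis) against the log2 of the mean normalized abundance plus 1 (x axis) for the 23666 tested genes. The 1456 genes called higher reach 8.88 on the y axis and the 549 called lower reach -7.98.

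Genes that maintain DNA methylation rose. Of the 12 in the list, 10 were higher and 0 lower over all genes tested, and 10 and 0 when adjusted over the list alone, with a median log2 fold change of 1.33. DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191), the remodeler that opens heterochromatin to the methyltransferases, rose from 594 ± 19.96 to 2103 ± 87.1 (SD, n = 2 each; log2 fold change 1.82 ± 0.09, limma adjusted p = 0.000387). MET1 (AT5G49160, chromosome 5, 19932114 to 19938470), the CG methyltransferase, rose from 2547 ± 237 to 4663 ± 156 (log2 fold change 0.88 ± 0.09, limma adjusted p = 0.0028). The VIM genes encode proteins that bind hemimethylated DNA and act with MET1. VIM1 (AT1G57820) rose from 1236 ± 76.8 to 2814 ± 25.3, VIM3 (AT5G39550) from 615 ± 20.7 to 1715 ± 110, and VIM6 (AT4G08590) from 208 ± 21.2 to 751 ± 16.2. VIM2 (AT1G66050) rose from 76.9 ± 1.86 to 628 ± 21.0, with a log2 fold change of 3.01 ± 0.17, against 6.50 ± 0.50 for VIM4 and 4.35 ± 0.86 for VIM5 (AT1G57800, at 0 and 3.07 in cmt3 and 60.7 and 26.5 in the labelled triple mutant). VIM2, VIM4 and VIM5 are close copies of their neighbours, and the split of reads among them is uncertain. Of the histone H3 lysine 9 methyltransferases that act with CMT3, SUVH4 (AT5G13960) rose from 682 ± 11.1 to 1444 ± 30.1 and SUVH5 (AT2G35160) from 175 ± 23.2 to 304 ± 11.4, while SUVH6 (AT2G22740) was at 401 ± 16.5 and 417 ± 9.98 (adjusted p = 0.871). CMT2 (AT4G19020), the CHH methyltransferase of heterochromatin, was at 1461 ± 139 and 1495 ± 43.1 (adjusted p = 0.893), and the sign of its log2 fold change was not stable (0.04, and -0.06 without cmt3 replicate 2). The list was higher than other genes by camera with a preset correlation (adjusted p = 8.62e-13) but not at the threshold with an estimated correlation (adjusted p = 0.086). MET1 (adjusted p = 0.0686), VIM5 (0.144) and SUVH5 (0.105) lost their calls in limma without the trend, SUVH5 also without cmt3 replicate 1 (0.0955) or 2 (0.0523) and with median centring (0.0539), and VIM5 without cmt3 replicate 1 (0.0923) or with a pseudocount of 0.1 (0.102).

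In the RNA-directed DNA methylation list, 5 of 24 genes rose and 0 fell (7 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 0.17. CLSY4 (AT3G24340) and CLSY3 (AT1G05490), remodelers that recruit RNA polymerase IV, rose from 28.2 ± 11.7 to 428 ± 41.1 and from 45.4 ± 8.75 to 141 ± 18.9 (SD, n = 2 each). AGO6 (AT2G32940) rose from 149 ± 54.2 to 698 ± 4.90, the RNA-dependent RNA polymerase gene RDR2 (AT4G11130) from 304 ± 1.17 to 785 ± 0.593 and the dicer gene DCL3 (AT3G43920) from 472 ± 24.2 to 737 ± 27.1. The RNA polymerase IV and V subunit genes NRPD1 (355 to 482) and NRPE1 (827 to 941) and the methyltransferase gene DRM2 (679 to 536) did not pass the test. The camera adjusted p of the list was 0.00264, and was 0.498 with an estimated correlation and 0.0678 by fry, and leaving out cmt3 replicate 2 gave 3 genes higher, a median of 0.02 and a camera adjusted p of 0.18. The median was 0.09 without labelled triple mutant replicate 2 and 0.10 with quantile normalization, and limma without the trend called 3 genes higher. CLSY3 lost its call without cmt3 replicate 1 (adjusted p = 0.0531) or 2 (0.0651), and DCL3 without cmt3 replicate 2 (0.0528). AGO6 (adjusted p = 0.0708), DCL3 (0.0873) and CLSY3 (0.0636) lost theirs in limma without the trend, while DRM1 passed there (0.0377) and with no filter on low values (0.0289).

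Of 9 DNA demethylation genes, 2 rose and 0 fell, also when adjusted over the list alone. The DNA phosphatase gene ZDP (AT3G14890) rose from 743 ± 46.8 to 1610 ± 64.3, and the demethylase gene ROS1 (AT2G36490), whose expression is known to follow DNA methylation, rose from 2758 ± 532 to 4281 ± 4.67 (SD, n = 2 each; log2 fold change 0.65 ± 0.13). The list's median log2 fold change was -0.09, its mean 0.16 and its camera direction up, so these differ in sign, and its camera adjusted p was 0.59. The median was 0.05 without cmt3 replicate 1 and 0.02 without labelled triple mutant replicate 1. Among loci silenced by DNA methylation, 2 of 5 were tested and 1 fell. QQS (AT3G30720), an orphan gene whose silencing depends on methylation of upstream repeats, fell from 771 ± 81.2 to 39.6 ± 12.2 (log2 fold change -4.28 ± 0.26, limma adjusted p = 0.000551). SDC (AT2G17690) was at 9.52 and 5.43 in cmt3 and was listed at 0 in both labelled triple mutant libraries (limma adjusted p = 0.0732), and both genes were lower when adjusted over the list alone. SDC passed in limma without the trend (adjusted p = 0.0433) and with no filter on low values (0.0403). ROS1 lost its call in limma without the trend (adjusted p = 0.211).

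Genes of the DREAM complex and the E2F family rose. In the DREAM and E2F list, 15 of 20 genes rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 fold change of 0.98. ALY1 (AT5G27610), a LIN9-like DREAM subunit, rose from 274 ± 15.9 to 1583 ± 9.39 (SD, n = 2 each), the E2F genes E2FA (AT2G36010) and E2FC (AT1G47870) from 245 ± 2.03 to 807 ± 40.7 and from 518 ± 46.1 to 1746 ± 32.3, and the atypical E2F gene DEL3 (AT3G01330) from 181 ± 1.70 to 948 ± 141. TCX2, TCX3 and TCX7, relatives of the mutated genes, also rose (log2 fold changes of 1.21, 1.58 and 1.89), while TSO1 did not pass (0.26, limma adjusted p = 0.145). Camera gave the list an adjusted p of 2.53e-18, and the adjusted p was 0.0893 with an estimated correlation.

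Of 38 DNA replication genes, 31 rose and 0 fell (34 and 0 adjusted over the list alone), with a median log2 fold change of 0.90. ORC1B (AT4G12620) of the origin recognition complex rose from 311 ± 11.6 to 964 ± 20.8, the chromatin assembly gene FAS1 (AT1G65470) from 561 ± 46.5 to 1679 ± 4.47, the DNA polymerase delta gene POLD1 (AT5G63960) from 818 ± 28.1 to 2000 ± 56.1 and the DNA polymerase epsilon gene TIL1 (AT1G08260) from 1162 ± 31.0 to 2861 ± 119 (SD, n = 2 each). TIL1 and TIL2 are close copies whose reads may be shared. The genes that did not pass included MCM6 (545 to 781) and CDC45 (228 to 349). Camera gave an adjusted p of 1.02e-26, and 0.086 with an estimated correlation. Limma without the trend called 13 of these genes higher, and MCM6 passed without cmt3 replicate 1 (adjusted p = 0.0408).

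Mitotic genes rose almost throughout the list, with 31 of 32 higher and 0 lower (32 and 0 adjusted over the list alone) and a median log2 fold change of 1.17. The condensin genes SMC2 (AT5G62410) and SMC4 (AT5G48600) rose from 961 ± 87.5 to 2834 ± 185 and from 1042 ± 45.9 to 2880 ± 4.81 (SD, n = 2 each). The Aurora kinase genes AUR1 (AT4G32830) and AUR3 (AT2G45490) rose from 413 ± 7.22 to 1340 ± 89.8 and from 90.7 ± 6.27 to 546 ± 49.3. CYCB2;1, the exception, was at 85.6 and 157 (limma adjusted p = 0.0899). For this list camera gave an adjusted p of 8.41e-33, and 0.086 with an estimated correlation. Limma without the trend called 18 mitotic genes higher.

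DNA repair and meiosis genes rose as well. In the repair list 14 of 17 tested genes rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 fold change of 1.00. The recombination gene RAD54 (AT3G19210) rose from 265 ± 18.7 to 1924 ± 38.3, PARP2 (AT4G02390), which modifies proteins at DNA breaks, from 351 ± 5.94 to 1528 ± 20.03, BRCA2B (AT5G01630) from 480 ± 44.4 to 1789 ± 112 and the checkpoint kinase gene ATR (AT5G40820) from 260 ± 28.8 to 909 ± 16.7 (SD, n = 2 each). In the meiosis list 11 of 13 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 2.35. The meiotic recombinase gene DMC1 (AT3G22880) rose from 435 ± 36.0 to 4004 ± 161, with a log2 fold change of 3.20 ± 0.09. The chromosome axis gene ASY1 (AT1G67370) rose from 114 ± 24.6 to 1606 ± 59.5, and the crossover genes MSH4 (AT4G17380) and MSH5 (AT3G20475) from 41.05 ± 5.93 to 368 ± 20.9 and from 88.4 ± 10.98 to 816 ± 13.6. Of the near-identical ZYP1 copies, ZYP1A was called (log2 fold change 2.35) and ZYP1B was not (0.85, adjusted p = 0.239), and reads may be shared between them. The camera adjusted p was 3.28e-17 for repair and 5.91e-17 for meiosis, and 0.0919 and 0.086 with an estimated correlation. Limma without the trend called 8 repair genes higher.

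**Figure D3:**
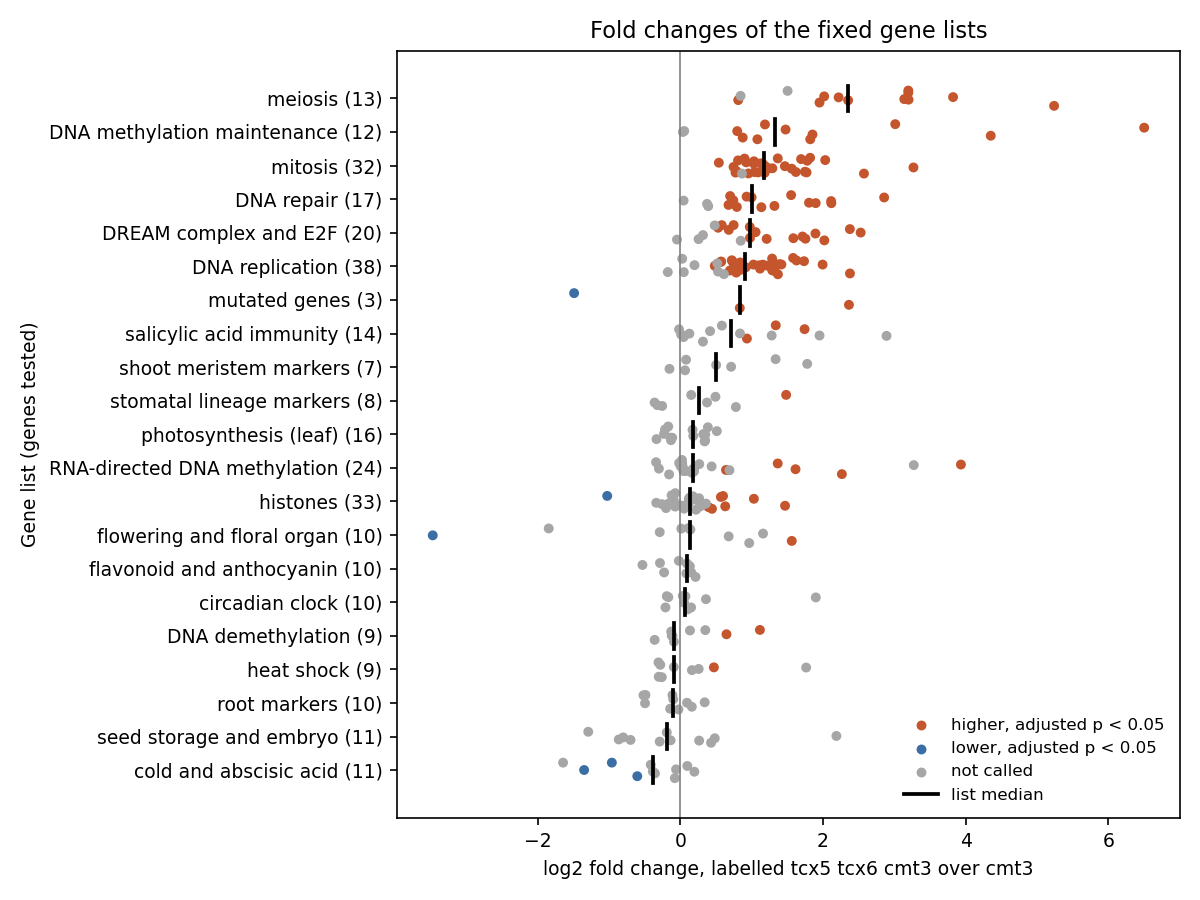
Log2 fold change of the labelled triple mutant over cmt3 (x axis) for each tested member (points) of the fixed gene lists (y axis, number tested in parentheses), with the list median as a black bar and members called higher or lower in colour. The meiosis list has the highest median, at 2.35, and the methylation maintenance, mitosis, repair, DREAM and E2F, and replication lists have medians from 0.90 to 1.33.

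Most core histone genes did not pass the test. Of 33 histone genes, 7 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 0.13. The H2A.Z genes HTA8 (AT2G38810) and HTA11 (AT3G54560) rose from 411 ± 74.8 to 1130 ± 5.68 and from 1327 ± 62.1 to 2713 ± 104 (SD, n = 2 each). The H3.1 genes HTR2 (AT1G09200) and HTR13 (AT5G10390) rose with log2 fold changes of 0.57 and 0.63, and H1.3, a linker histone gene induced by stress, fell (-1.02). Histone genes of a class are close copies, so the split of reads among them is uncertain. The camera adjusted p was 0.00225, and 0.163 with an estimated correlation. Without cmt3 replicate 2 there were 4 histone genes higher, with HTR13 (adjusted p = 0.0548), HTA13 (0.0501) and HTA6 (0.0511) losing their calls, and HTA8 (0.0549), HTR2 (0.1), HTR13 (0.101) and H1.3 (0.143) lost theirs in limma without the trend, which called 1 histone gene higher and 0 lower. With median centring the list median was 0.08.

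A set of salicylic acid immunity genes rose and a set of cold genes fell. Of 14 immunity genes, 3 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 fold change of 0.71. WRKY70 (AT3G56400) rose from 4266 ± 467 to 8130 ± 205, the salicylic acid biosynthesis gene SID2 (AT1G74710) from 398 ± 47.7 to 1012 ± 173 and the pathogenesis-related gene PR2 (AT3G57260) from 307 ± 118 to 1026 ± 382 (SD, n = 2 each). PR1 (AT2G14610) was at 424 and 92.1 in cmt3 and at 1085 and 2004 in the labelled triple mutant (limma adjusted p = 0.0525). For immunity the camera adjusted p was 6.37e-05, and 0.137 with an estimated correlation. Of 11 cold and abscisic acid genes, 0 rose and 3 fell (0 and 4 adjusted over the list alone), with a median log2 fold change of -0.38. CBF1 (AT4G25490), a transcription factor of cold acclimation, fell from 469 ± 30.7 to 185 ± 30.0, and its known targets COR15A (AT2G42540) and COR15B (AT2G42530) fell from 15471 ± 3452 to 7897 ± 1109 and from 5709 ± 1119 to 3723 ± 99.3. CBF3 was at 69.2 ± 7.80 and 21.8 ± 6.02 (adjusted p = 0.0518). For cold genes the camera adjusted p was 0.00264, and 0.194 with an estimated correlation and 0.0532 by fry. Without cmt3 replicate 1 the cold list had a median of -0.19 and 0 lower calls, and without cmt3 replicate 2 a median of -0.63 and 5. Without the trend none of these 6 calls held (adjusted p of 0.0594 to 0.242). Without cmt3 replicate 1 the adjusted p was 0.0735 for PR2, 0.0545 for CBF1, 0.0883 for COR15A and 0.051 for COR15B, and PR1 passed (0.0351). PR1 also passed with no filter (0.045), a filter at 5 (0.0492) and median centring (0.0484), CBF3 with quantile normalization (0.0432), the filter at 5 (0.0465) and median centring (0.0453), and COR15B did not with a pseudocount of 0.1 (0.0592). Without cmt3 replicate 2 it was 0.0512 for SID2, 0.131 for PR2 and 0.0579 for CBF1, and WRKY38 (0.0253) passed as higher and KIN2 (0.0316), RAB18 (0.0362) and RD29A (0.0423) as lower.

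Lists that mark organs, cell types or the state of the plants mostly did not pass. None of 16 photosynthesis genes, 10 root markers, 7 shoot meristem markers, 11 seed genes, 10 flavonoid genes or 10 clock genes was called by limma, and the counts adjusted over each list alone were also 0. Their camera adjusted p was 0.333, 0.514, 0.234, 0.758, 0.909 and 0.59, and their median log2 fold changes were 0.18, -0.10, 0.50, -0.19, 0.09 and 0.06. Lists moved past the threshold in single settings: with quantile normalization, camera gave 0.0448 for photosynthesis; without cmt3 replicate 1, camera gave 0.0123 for photosynthesis and 0.00173 for root markers, and without labelled triple mutant replicate 2 it gave 0.0414 for flavonoid genes. Single genes did as well: LHCB3 passed as higher with quantile normalization (adjusted p = 0.0194) and without cmt3 replicate 1 (0.0463), the clock gene LUX in the same settings (0.0317 and 0.0441), and the root iron transporter gene IRT1 without cmt3 replicate 2 (0.0414). Leaving out single libraries moved these medians by over 1.5 times, and for root, seed and flavonoid genes across 0. Without cmt3 replicate 1 the median was 0.34 for photosynthesis, -0.44 for root markers, 0.31 for shoot meristem markers and -0.99 for seed genes, and without cmt3 replicate 2 it was 0.01, 0.28, 0.28 and 0.61 for these and -0.13 for flavonoid and 0.03 for clock genes. Without labelled triple mutant replicate 1 it was 0.24 for seed, -0.17 for flavonoid and 0.01 for clock genes, and without replicate 2 it was -0.06 for root markers and -0.57, 0.27 and 0.15 for seed, flavonoid and clock genes. The shoot meristem markers moved up on balance by fry (adjusted p = 0.00268). Root markers differed between the cmt3 replicates, with the Casparian strip gene CASP1 at 1327 and 2330 and CASP2 at 407 and 872, and this difference was not tested. POLAR (AT4G31805), a stomatal lineage gene, rose from 129 ± 7.47 to 362 ± 16.5 as the 1 call among 8 such genes (camera adjusted p = 0.273). Of 10 flowering genes, SEP3 (AT1G24260) rose from 271 ± 17.0 to 814 ± 207 and FLC (AT5G10140), a repressor of flowering, fell from 17.0 ± 3.63 to 0.8 ± 1.13, with a camera adjusted p of 0.758 and a median (0.13, and 0.47 and 0.22 without cmt3 replicates 1 and 2) and mean (-0.10) of opposite sign. HSP90.1 (AT5G52640), from 891 ± 77.1 to 1234 ± 8.13, was the 1 call among 9 heat shock genes, whose median was -0.09 and mean 0.16 (camera adjusted p = 0.909). That median was 0.16 with a filter at 5, -0.21 and 0.35 without cmt3 replicates 1 and 2, and -0.24 and 0.27 without labelled triple mutant replicates 1 and 2. The flavonoid list also had a median and mean (-0.03) of opposite sign. Both SEP3 and FLC lost their calls without cmt3 replicate 1 (adjusted p = 0.0643 and 0.145) or 2 (0.0652 and 0.108), and HSP90.1 without cmt3 replicate 1 (0.0695). FLC was also not called with a pseudocount of 0.1 (0.12) or a filter at 5 (0.0642). SEP3 (adjusted p = 0.0799), FLC (0.0957) and HSP90.1 (0.167) lost theirs in limma without the trend.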

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

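Of these alternatives, median centring and all alternatives for the mutated genes were chosen after seeing the data. So were the settings of the gene list tests other than the estimated correlation, fry and the replicate block. The methylation maintenance list was an exception, since its other settings apart from median centring were planned. Count-based alternatives were not run because the values are not counts. Counts of genes higher and lower stayed within 1.5 times the 1456 and 549 of the comparison with quantile normalization (1450 and 724), no filter (1473 and 573), a filter at 5 (1487 and 580), a pseudocount of 0.1 (1369 and 487) and median centring (1349 and 743, of which 1347 and 549 were the same genes as in the comparison). Limma without the trend called 586 higher and 135 lower, of which 528 and 88 were the same genes as in the comparison. It gave CMT3 a log2 fold change of 0.83 that no longer passed (limma adjusted p = 0.111). The fold changes are the same in both fits, which differ in how the spread between libraries is moderated. The prior degrees of freedom were 1.34 without the trend and 4.32 in the comparison. How much of the loss of calls this accounts for was not tested. An adjusted p under 0.01 left 780 and 173, and 2-fold or more left 776 and 190, by construction. Leaving out each library gave from 0 to 1281 higher, from 0 to 530 lower and from 0 to 9 methylation maintenance genes, with the counts of 0 in the fits without a labelled triple mutant library, where 1 residual degree of freedom comes from the cmt3 pair and the lone library is assumed to vary like it. Over those fits the log2 fold change ranged from -1.54 to -1.43 for TCX5, from 2.28 to 2.45 for TCX6 and from 0.68 to 0.99 for CMT3, and camera for methylation maintenance from 5.12e-12 to 2.21e-08. Camera passed 9 to 12 of the 21 lists. With an estimated correlation the methylation maintenance list had a camera adjusted p of 0.086 and 0 of 21 lists passed. The estimate was below the preset 0.01 for maintenance (-0.055), replication (-0.005), meiosis (-0.074), histone (-0.005), immunity (-0.011) and cold genes (0.008). For the mitosis, repair, DREAM and E2F, and RNA-directed DNA methylation lists it was 0.058 to 0.19. These estimates rest on the residuals of 4 libraries and cannot decide whether correlation between members is the reason. With an estimated correlation, camera also takes p-values from the few residual degrees of freedom of 4 libraries. With the preset correlation it uses the number of genes. The settings thus differ in more than the correlation, and these parts were not tested apart. The odds ratio of a CHR-like site in genes called higher was 1.17 at 1000 bp and no longer passed (adjusted p = 0.0889). The cause was not tested. No gene named by the rule that was called in the comparison, camera test that passed or odds ratio above changed direction, but of the genes not called CMT2, CASP2 and CUC2 changed sign without cmt3 replicate 2 (log2 fold changes of -0.06, 0.03 and -0.01), FUS3 without labelled triple mutant replicate 1, SUVH6 with quantile normalization and CMT2 with median centring, and the medians of 5 lists that camera did not pass changed sign, those of demethylation, flavonoid, root and seed genes without single libraries, and that of heat shock genes without single libraries and with the filter at 5. Quantile normalization, a filter, the pseudocount of 0.1 or median centring also moved the medians of the demethylation, root, flowering, seed, heat shock, flavonoid and clock lists by over 1.5 times. Examples are seed genes, from -0.19 to -0.70 with the filter at 5, and clock genes, from 0.06 to 0.01 with median centring. The labels give both genotypes replicates 1 and 2 but do not say that the numbers pair the libraries, and deviations from the group means correlated at 0.000633 over all tested genes and -0.05 at a mean of 100 or more. With the replicate number as a block, 1314 genes were higher, 473 lower, 9 methylation maintenance genes were higher and 10 lists passed. Under the block SUVH5 (limma adjusted p = 0.0698) and FLC (0.0583) lost their calls. The immunity genes PR1 (limma adjusted p = 0.0495) and PR5 (0.0222) passed as higher there, so that list had 5 genes higher, against 3 in the comparison. Of 109 named genes, 88 stayed on the same side of the threshold without the trend, 106 with quantile normalization, 106 with the pseudocount of 0.1 and 39 without either labelled triple mutant library. Unknown depth limits what can be said of low genes. The simulated fit found 4.48% of genes changed 1.5-fold, with 200 changed genes among 23417. The data gave 2005 calls, and the Benjamini-Hochberg threshold is looser when more genes change, so this share does not carry over to the data.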

Other observations

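The tests chosen only after the result was seen were those on exchanged labels, on reads shared by TCX5 and TCX6, on dividing cells, on flower buds, on E2F sites in the mitosis and meiosis lists, on values near the floor, on non-coding genes, on adjacent genes, on gene density in genes lower 2-fold or more, and on words in product names.

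Words in the product names of called protein-coding genes were tested against all tested protein-coding genes in 1538 one-sided Fisher tests, where genes are not independent replicates. Kinesin was in the names of 18 tested genes, of which 10 were called higher (1.15 by chance, adjusted p = 6.68e-06), among them the phragmoplast orienting kinesins POK1 (607 ± 28.9 to 3419 ± 64.4, SD, n = 2 each) and POK2 (1012 ± 80.6 to 3465 ± 42.8). Structural maintenance of chromosomes proteins were likewise overrepresented, with 7 of 11 genes with the word chromosomes higher (adjusted p = 0.000174), among them SMC6A (155 ± 1.52 to 1300 ± 170) and SMC5 (621 ± 37.7 to 1008 ± 78.5, not called in limma without the trend, adjusted p = 0.0977, or without cmt3 replicate 2, 0.0591). Polymerase was in the names of 143 genes, of which 24 were higher (9.15 by chance, adjusted p = 0.00147), and these include the adjacent RNA-dependent RNA polymerase genes AT2G19910 (46.7 ± 16.4 to 582 ± 58.2), AT2G19920 (60.03 ± 12.4 to 236 ± 25.03) and AT2G19930 (428 ± 9.18 to 1146 ± 63.6). Chromatin was in 26 names with 9 higher (adjusted p = 0.00207), among them the remodeler CHR24 (730 ± 57.1 to 2361 ± 95.9), and agenet, a domain of chromatin readers, in 13 with 6 higher (adjusted p = 0.00576).

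Among genes called lower, MATE efflux carriers were 7 of 52 (1.18 by chance, adjusted p = 0.0102), led in abundance by AT1G61890 (6211 ± 569 to 3116 ± 39.3, SD, n = 2 each; adjusted p = 0.054 in limma without the trend). Cupins were 5 of 28 (adjusted p = 0.0215), of which AT5G39110 (129 ± 74.1 to 4.99 ± 4.58), AT5G39120 (198 ± 62.0 to 26.2 ± 9.87), AT5G39150 and AT5G39180 lie near each other on chromosome 5 and are close copies, so their values are uncertain, and all 4 lost their calls in limma without the trend (adjusted p of 0.0648 to 0.116) and without cmt3 replicate 1 (0.0519 to 0.106) or 2 (0.068 to 0.112). TIR-NBS-LRR disease resistance genes were 8 of 86 (adjusted p = 0.0373), among them AT1G63750 (2440 ± 269 to 1282 ± 11.2) and WRR4 (5768 ± 612 to 3949 ± 166), which lost their calls in limma without the trend (adjusted p = 0.0686 and 0.163), WRR4 also without cmt3 replicate 1 (0.0552). Glycine-rich proteins were 7 of 59 (adjusted p = 0.0215).

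TCX6 rose in the libraries labelled tcx5 tcx6 cmt3. Reads of TCX5 placed on TCX6 are argued against as the whole cause, since the sum of both genes was 1.38 times as high there. That sum was 4.15 times the larger SD above cmt3, and misplaced reads stay open as a part of the rise. Transcription spreading along the chromosome is argued against, since the tested neighbours did not pass (the larger change was a log2 fold change of -0.2, for COV1). Exchanged group labels cannot be told apart from the labels as given by these genes, because TCX5 fell (log2 fold change -1.49) while TCX6 rose. A candidate explanation that stays open and was not tested is a transcript that starts in or reads through an insertion, and a loss of repression of TCX6 by the complex itself is open as well.

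The replication, mitosis, repair and meiosis lists were higher by camera with the preset correlation, with adjusted p of 0.086, 0.086, 0.0919 and 0.086 with an estimated correlation, and the histone list also passed (0.00225, and 0.163 with an estimated correlation) and the shoot meristem markers moved up by fry (adjusted p = 0.00268). A larger share of dividing cells as the whole cause is argued against by the 13 H3.1 and H4 genes, whose median log2 fold change was 0.22 (SD 0.285 over genes, the highest 0.63, 3 called higher) against 0.90 for replication, so that a larger share stays open as a part of it, while flower buds stay open for meiosis, because the 7 floral organ genes (median log2 fold change 0.68, SD 1.12, against 2.35 for meiosis) had a median value of 10.5 in cmt3, near the floor, and SEP3 rose (1.56). An E2F site was in 9.34% of promoters of genes called higher and 4.70% of others (odds ratio 2.09, 95% interval 1.72 to 2.53, Fisher adjusted p = 6.27e-12). This goes with a response through E2F sites for part of the genes. An MSA core, a different site, was in 43.2% and 34.1% (odds ratio 1.47, Fisher adjusted p = 1.07e-11). In the mitosis and meiosis lists 0 of 45 promoters had the E2F site (upper exact 95% limit 7.87%), so most of these promoters lack this form of it. Sites of another form or outside the 500 bp upstream were not searched here, so a response through them stays open. At the 4.70% of other genes, 0 of 45 has a chance of 0.115, so these lists cannot be told from that share. The site was in 15 of 38 replication promoters, but in 1 of 12 for methylation maintenance and 1 of 24 for RNA-directed DNA methylation. An MSA core was in 23 of 32 mitosis promoters and in 5 of 12 for methylation maintenance. The maintenance list is too short to tell its shares from those of other genes. Among genes called lower no site passed (adjusted p = 0.0692 for E2F), and the CHR-like site had an odds ratio of 1.14 among genes called higher (adjusted p = 0.0382), and 1.17 at 1000 bp (adjusted p = 0.0889).

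The genes called lower had a median cmt3 value of 1115, above the floor. They are higher in cmt3 by selection, so this does not cover values at or near 0 in the labelled triple mutant. A single linked segment is argued against as the whole cause. Every chromosome held lower calls, from 84 on chromosome 4 to 144 on chromosome 1. The 1 Mb bin with the most, on chromosome 2 from 6000001 to 7000000, held 12 of 549 (2.19%), against 0.435% of the tested genes. A segment behind part of the falls therefore stays open. Differences between the lines at several places in the genome were not tested and stay open. They lay in slightly gene-poorer regions, with a median of 132.0 protein-coding genes within 250 kb against 136 in matched genes (95% of draws from 135 to 138, p = 0.0001 by two-sided permutation), and in the 190 genes lower 2-fold or more it was 122.5 (p = 2e-05 by two-sided permutation, the smallest the 100000 draws can give). Whether placement accounts for the falls stays open, since for all lower genes both the bound written for it (a lower median) and the bound written against it (within 5 genes) were met. Annotated non-coding genes were 36 of 549 lower calls (6.56%) against 4.49% of all other tested genes (odds ratio 1.49, 95% interval 1.03 to 2.11, Fisher p = 0.0286), and may mark a small part of the lower genes, as a hypothesis. Among higher calls they were 11 of 1456 (0.755%), so the odds ratio of 9.21 for lower against higher calls comes mostly from the higher calls.

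Lower genes were next to each other in 37 pairs against 12.8 in random draws (6 to 20), and higher genes in 144 against 90.6 (73 to 108), each at p = 0.0001 by one-sided permutation, the smallest the draws can give. Abundant genes also changed, named here after their values were seen: ESM1 (AT3G14210), a modifier of glucosinolate breakdown, was at 53872 and 42541 in cmt3 and at 4248 and 4272 in the labelled triple mutant (log2 fold change -3.49 ± 0.14, SE; limma adjusted p = 0.000325), and PHI-1 (AT1G35140) was at 630.2 and 855 against 3493 and 3835 (log2 fold change 2.32 ± 0.15, limma adjusted p = 0.000596).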
